A study of Mus musculus with 2 samples.

How the data were processed

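H3K4me2 was measured by chromatin immunoprecipitation and sequencing in forebrain tissue of mice on the day of birth (age 0 days), in 2 biological replicates. Per the labels, each replicate was a pool of animals of both sexes, replicate 1 coming from 15 mice, and both libraries were made by one laboratory. The labels give 1 group, so no groups of samples were compared. All comparisons were between genes or regions within this tissue, with the value of each replicate beside the main value.

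The data used here were 4 peak lists in narrowPeak format on mm10: 1 per replicate, 1 pooled list that the deposited notes derive from the alignments of both replicates together, and 1 list called replicated, derived from the other 3. Peaks had thus been called per sample and on the pool. The peak caller, its version, its threshold, the background it used and the rule of the replicated list are not given in the sources used here, although the labels name a possible control experiment. The lists held 42315, 47258, 47647 and 36496 peaks. Every entry of the replicated list was found unchanged in the pooled list, and 90.2% of its peaks were overlapped by peaks of both replicates over at least 50% of the shorter peak. By an overlap of any length, 32990 of its 36496 peaks were met by peaks of both replicates. The others lacked a peak in at least 1 replicate's own list, so an entry in this list does not by itself mean a call in both. The replicated list served as the main list.

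Each peak had a fold enrichment (a ratio), a -log10 p-value, a -log10 q-value and a summit offset in bases, all computed by the authors, and the column order of the format was checked on the values. What the fold is relative to is not given in the sources used here, so folds served to describe, rank or filter peaks within a list, to correlate the replicates and, in the closing section, to compare X promoters with autosomal and with other X promoters. The authors' lowest -log10 p-values were 2.03, 2.05, 2.16 and 2.17 for replicate 1, replicate 2, the pooled and the replicated list. Peak lists do not give sequencing depth, so no value was scaled by depth. Agreement between replicates, and exact or permutation intervals over genes, give the precision.

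Gene models were GENCODE release M21 on GRCm38 (mm10). The build was checked: every peak ended within its chromosome, and 99.9% of 27907 annotated start codons read ATG in the genome. Genes were the 21911 protein-coding genes of chromosomes 1 to 19, X and Y with a unique symbol, 27 duplicate symbols being left out, with 93477 TSSs. Peaks on unplaced contigs (16 in each of 3 lists, 13 in the main list) were left out of the comparisons. A promoter was marked when a peak lay within 1 kb of any annotated TSS of the gene. A peak counted for every gene with a TSS within 1 kb of it, so a marked gene can share its peak with a neighbour's promoter. Breadth was the number of bases covered within 5 kb of the gene's TSS with the most covered bases, among marked genes. Distal peaks lay more than 2.5 kb from all 132629 TSSs of any gene type, and each was assigned to the nearest protein-coding TSS within 100 kb. Domains were peaks joined over gaps of up to 1 kb. CpG ratios (observed over expected) were computed within 500 bases on each side of the TSS and put into 5 classes of equal size. A peak's location was the first class it overlapped in the order promoter (of any gene type), exon, intron, with all others intergenic, beside 100 random placements on known bases.

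The 19 gene lists (pallial, subpallial, pan-neuronal, synapse, radial glia and astrocyte, oligodendrocyte, choroid plexus and ependyma, activity-regulated, microglia, vascular, erythroid, midbrain to spinal cord, Hox, liver, muscle, intestine and pancreas, germline, olfactory receptor and housekeeping), the 11 motifs, the tests and their alternatives were fixed before the data were examined. One erythroid gene, Ahsp, lacked an entry in the annotation and was not analysed here. Promoter and domain counts were compared by Fisher's exact test, breadth by permutation with 100000 random lists, and distal peaks by permutation with 10000 random lists matched on deciles of territory length (1000 draws for lists of over 200 genes). Lists with fewer than 3 usable members were not tested. Motif counts in 200 bases around summits were compared with the reversed motif by Fisher's exact test, the Rfx site being allowed 1 mismatch. For 4 motifs (CAGCTG, Rfx, nuclear factor I and CTCF) the reversed sequence holds a CpG that the motif lacks, so the report reads them against the windows 3 kb from the summit. Promoter calls of the replicates were compared by the exact McNemar test. All tests were two-sided, with Benjamini-Hochberg adjustment over the 19 lists or 11 motifs and a threshold of 0.05. Intervals of shares are exact 95% intervals, and log2 odds ratios carry the Haldane correction. Genes within a list can be neighbours or be regulated together, so a p over genes describes these lists in this tissue and not a variation between animals.

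Named genes followed a fixed rule. For each list these were the 3 marked members with the most covered bases (the first 2 marked ones in alphabetical order for mostly unmarked lists), the first 2 unmarked members in alphabetical order, and up to 4 members marked in 1 replicate only. Added to them were the genes at the 25 broadest domains that were among the 100 broadest in both replicates, the 10 genes with the most distal peaks and the 5 peaks with the highest fold. Members found in the broadest domains were named in full, by their membership, and the highest and lowest autosome by peak density were chosen after their values were seen.

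Alternatives were the pooled list, each replicate's own list, peaks with a -log10 q of at least 5, the 5'-most TSS only, promoter windows of 500 bases and 2.5 kb, CpG-matched backgrounds, a breadth window of 2.5 kb, all genes in place of marked genes, distal limits of 5 kb, assignment within 50 kb, no territory matching, joining gaps of 0 and 3 kb, the broadest 5%, whole peaks and windows 3 kb from the summit for motifs, an overlap of 50% of the shorter peak, -log10 p in place of fold, and lists of equal length. Keeping 1 member per 100 kb of a list was an alternative chosen after seeing the data. The member at the lowest position was kept, among marked members for breadth and domains. A call was taken as reversed when its direction changed and at least 1 of the 2 values passed its test. Another 7 gene lists (diencephalon regulators, eye and retina, imprinted, clustered protocadherin, clustered histone, keratin and vomeronasal receptor genes) were added after the design was fixed and before the result of any list was computed. A list of 5 genes known to escape X inactivation was added for a test of the X chromosome.

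Of the steps, interval overlap, promoter marking, breadth, distal peaks, broadest domains and the motif scan were tested on simulated data, and the others were not. Overlaps of 2032 simulated intervals matched bedtools without a difference, and a string search matched the motif scan at every position of 220 simulated sequences. Random lists of 20 genes were called in 0.105% of promoter tests and 0.132% of breadth tests. Lists of 20 with all promoters marked were called in 100% of runs, those with 19 marked in 2% and those with 3 marked in 100%. Breadth increases of 1.5-fold were called in 50% and of 2.5-fold in 100% of runs. Lists of genes with large territories were called in 92.5% of distal tests without matching and in 0% with matching, and lists with 5 times the peaks in 100%. In the domain test random lists were called in 0%, lists with 3 planted members in 0% and lists with 10 in 100% of runs. In the promoter, breadth and domain runs, the lists beside the planted list were random. Values there were drawn independently of CpG ratio and of neighbouring genes. These rates need not hold for the real lists, many of which passed together. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pysam 0.24.0 and matplotlib 3.10.9, with samtools 1.23.1 and bedtools 2.31.1.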

Results

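H3K4me2, a histone mark of active and primed promoters and enhancers, was found at the promoter of all 20 tested genes of pallial excitatory neurons and all 21 tested genes of subpallial GABAergic neurons in the newborn mouse forebrain. A promoter counted as marked when a peak lay within 1 kb of an annotated transcription start site (TSS). Marking was likewise complete for the 20 pan-neuronal genes, the 16 activity-regulated genes and the 24 housekeeping genes, and each of these 5 lists was complete in replicate 1 and in replicate 2 (n = 2 biological replicates). Among the genes of mature synapses and channels 17 of 18 were marked (94.4%, exact 95% interval 72.7 to 99.9), the exception being Vip, which encodes an interneuron neuropeptide. Radial glia and astrocyte genes were marked at 19 of 20 promoters (95%, 75.1 to 99.9). There S100b, encoding a glial calcium-binding protein, lacked a peak in both replicates, and Gfap, encoding the astrocyte intermediate filament, was called in replicate 2 (fold 4.01) but not in replicate 1, where peaks covered 739 bases within 5 kb of the TSS and none lay within 1 kb. Fold is the enrichment of a peak as the authors gave it, and the report uses it to describe and rank peaks and to compare the replicates. Against 66.8% of all 21911 protein-coding genes (14643 marked), all 7 lists were higher by Fisher's exact test, two-sided, after Benjamini-Hochberg adjustment over 19 lists. In this exact test the log2 odds ratios were 4.35 for the pallial list (adjusted p = 0.0011), 4.42 for the subpallial (adjusted p = 8.8e-04), 4.35 for the pan-neuronal (adjusted p = 0.0011) and 4.04 for the activity-regulated list (adjusted p = 0.0044). The same exact test gave 4.61 for the housekeeping (adjusted p = 3.6e-04), 2.54 for the synapse (adjusted p = 0.016) and 2.69 for the radial glia list (adjusted p = 0.011). For the 5 complete lists the corrected ratio is set by the list's size, so its differences between them carry no meaning. Its 95% interval was wide, 0.30 to 8.40 for the pallial and -0.024 to 8.09 for the activity-regulated list. With only the 5'-most TSS of each gene, radial glia genes did not pass (75% against 63.1%, exact test adjusted p = 0.42).

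Genes of microglia, of the liver, of the germline and of olfactory receptors were seldom marked. Microglia and macrophage genes were marked at 3 of 18 promoters (16.7%, exact 95% interval 3.58 to 41.4). Hexb, a lysosomal enzyme gene, and Irf8, a myeloid transcription factor gene, had peaks of fold 38.1 and 46.7, while Aif1, a macrophage calcium-binding gene, and C1qa, a complement gene, were unmarked, though peaks beyond 1 kb covered 398 bases within 5 kb of the TSS of C1qa. P2ry12, the microglial purine receptor gene, was called in replicate 1 only (fold 3.86). Liver genes were marked at 3 of 20 promoters (15.0%). The lipoprotein gene Apoa1 was called in replicate 1 only, although peaks beyond 1 kb covered 1380 bases within 5 kb of its TSS in replicate 2. In replicate 1 the covered bases, with the peak within 1 kb counted, were 1450. Apob was called in replicate 2 only and the bile acid receptor gene Nr1h4 in replicate 2 only and not in the main list, while the fetal serum protein genes Afp and Ahsg were unmarked. Germline genes were marked at 3 of 20 promoters (15.0%), including Dazl, an RNA-binding gene of germ cells (fold 25), and Smc1b, a meiotic cohesin gene (fold 19.3). Acrv1, an acrosome gene, and Ddx4, a germ-cell helicase gene, were unmarked. Of 1092 olfactory receptor genes 3 were marked (0.275%), among them Olfr1033 and Olfr658 with peaks of fold 7.23 and 9.20, while Olfr1 and Olfr10 were unmarked.

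Intestine and pancreas genes were marked at 3 of 14 promoters (21.4%). Lgr5, a Wnt-pathway receptor gene, had a peak of fold 43.8 and the homeobox gene Cdx1 one of fold 5.26, whereas its relative Cdx2 and the elastase gene Cela1 were unmarked. Muscle genes were marked at 8 of 22 promoters (36.4%), among them Actn3 (fold 33.3) and Ckm (fold 37.5) of the contractile and energy machinery, but not the actin gene Acta1, where peaks beyond 1 kb covered 2115 bases within 5 kb, or the myogenic factor gene Myf5. Erythroid genes were marked at 5 of 14 promoters (35.7%), including Epor, the erythropoietin receptor gene (fold 28.5), and Gypa, a red-cell surface gene (fold 31.1), but not the heme synthesis gene Alas2 or the erythroid regulator Gata1. By the same exact test these lists and those of the preceding paragraph were all lower than other genes. The log2 odds ratio in the exact test was -3.16 for microglia (adjusted p = 8.2e-05), -3.34 for liver (adjusted p = 1.7e-05), -3.34 for germline (adjusted p = 1.7e-05) and -2.73 for intestine and pancreas (adjusted p = 0.0014). The exact test gave -1.78 for muscle (adjusted p = 0.0086), -1.80 for erythroid genes (adjusted p = 0.028) and -9.53 for olfactory receptors, whose p was below the smallest number that the software stores. Muscle genes did not pass with a promoter window of 2.5 kb (54.5% against 68.0%, exact test adjusted p = 0.22).

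Other lists did not pass the adjusted threshold. Oligodendrocyte lineage genes were marked at 11 of 18 promoters (61.1%, log2 odds ratio -0.39, adjusted p = 0.69 by Fisher's exact test), with Gpr17, a receptor gene of maturing oligodendrocytes, and the myelin gene Mag unmarked. Choroid plexus and ependyma genes were marked at 9 of 14 (64.3%, -0.22, exact test adjusted p = 0.83), without the water channel gene Aqp1 or the ciliary motor gene Dnah5. Vascular and meningeal genes were marked at 14 of 20 (70.0%, 0.15, exact test adjusted p = 1). Cdh5, an endothelial cadherin gene, and the collagen gene Col3a1 were unmarked, the matrix genes Dcn and Lum were called in replicate 1 only, and the endothelial genes Pecam1 and Tek in replicate 2 only. Regulators of midbrain, hindbrain and spinal cord were marked at 17 of 19 promoters (89.5%, 1.80, exact test adjusted p = 0.061), without Pax7 and Phox2b. Hox genes, which pattern the trunk and hindbrain, were marked at 20 of 39 promoters (51.3%, -0.94, exact test adjusted p = 0.07). Hoxa10 and Hoxa11 were unmarked, Hoxb4, Hoxb5 and Hoxb9 were called in replicate 2 only and Hoxc10 in replicate 1 only.

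Many of these differences were smaller against genes of equal CpG content. Across 5 classes of rising CpG ratio, 2.62, 39.0, 94.2, 98.9 and 99.4% of promoters were marked. Against random lists matched on CpG class (permutation, two-sided, adjusted over 19 lists), only the pallial list was called higher (100% against 90.0%, adjusted p = 0.043). Lower in the permutation were Hox genes (51.3% against 92.3%, adjusted p = 0.0019), germline genes (15.0% against 65.0%, adjusted p = 0.0019), intestine and pancreas genes (21.4% against 57.1%, adjusted p = 0.0038) and olfactory receptor genes (0.275% against 9.07%, adjusted p = 0.0095). The permutation p-values of the Hox, germline and olfactory lists were the smallest that their numbers of draws can give. Hox genes lie in clusters, which this permutation counts as separate genes. With 1 member per 100 kb, the Hox genes kept were those at the lowest position of each cluster, Hoxa1, Hoxb13, Hoxc13 and Hoxd13. All 4 were marked, against 66.8% of other genes (Fisher's exact adjusted p = 0.37, no CpG matching). Even 4 of 4 did not pass as an excess, and each cluster also holds unmarked members. This setting therefore does not settle the part of clustering in the lower share. Microglia, liver, muscle and erythroid genes did not pass in the CpG-matched comparison, since CpG-matched genes were marked at 27.8, 30.0, 45.5 and 35.7% of promoters (permutation adjusted p = 0.46, 0.31, 0.88 and 1). Nor did the other 6 lists that were higher: CpG-matched genes were marked at 100% for the subpallial, activity-regulated and housekeeping lists, and at 85.0, 77.8 and 80.0% for the pan-neuronal, synapse and radial glia lists (permutation adjusted p = 0.087, 0.11 and 0.052). With matched lists already at 100%, this comparison could not show an excess for the subpallial, activity-regulated and housekeeping lists.

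**Figure D1:**
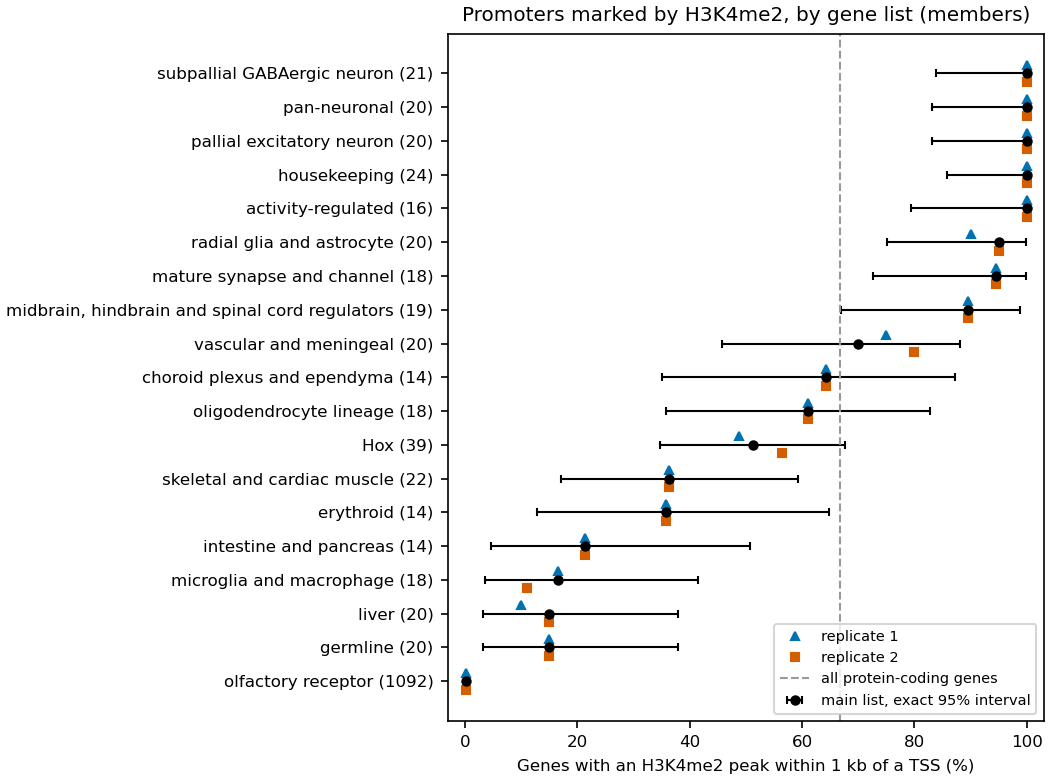
Share of genes with an H3K4me2 peak within 1 kb of a TSS (x axis, percent) for 19 gene lists (y axis, number of genes in brackets); black points are the main list with exact 95% intervals, blue triangles replicate 1, orange squares replicate 2, and the dashed line is all protein-coding genes. Pallial and subpallial lists were at 100%, liver and germline at 15.0%.

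Pallial and subpallial genes had broad marking around the TSS by their medians. Around the TSS of Pou3f3 and Pou3f2, POU factors of cortical neurons, and Lhx2, a regulator of cortical identity, peaks covered 10001, 9960 and 9780 bases within 5 kb on each side. Dlx1, a regulator of GABAergic neurons, Slc32a1, the vesicular GABA transporter gene, and Gad1, a GABA synthesis gene, had 10001, 10001 and 9834 covered bases. Pallial genes had a median of 7864 covered bases (7268 and 7575 in replicates 1 and 2, n = 20 genes) and subpallial genes 6361 (6314 and 5930, n = 21), beside 2481 over all marked promoters. Among pan-neuronal genes (median 5672.5 bases, n = 20) the widest were Celf4, an RNA-binding gene (9083), Tubb3, a neuronal tubulin gene (7496), and Elavl4, another RNA-binding gene (7194). Activity-regulated genes (median 5632, n = 16) were led by the nuclear receptor gene Nr4a3 (8291), the early response gene Egr3 (6829) and the synaptic scaffold gene Homer1 (6623). Radial glia and astrocyte genes (median 4811, n = 19) were led by Nfib and Pax6 (10001 each) and Nfia (9403), all encoding transcription factors of neural progenitors. Synapse genes (median 4177, n = 17) were led by the postsynaptic scaffold gene Dlg4 (8133) and the glutamate receptor genes Grin2b (7222) and Gria2 (6514), and housekeeping genes (median 3241.5, n = 24) by Ywhaz (6837), the ubiquitin gene Ubc (5495) and the actin gene Actb (5088). All 7 medians exceeded those of random lists of marked genes by a two-sided permutation test adjusted over 19 lists. The adjusted p was 6.3e-05 for pallial, subpallial, pan-neuronal, activity-regulated and radial glia lists, each from the smallest p that 100000 random lists can give (2e-05), 0.0018 for synapse genes and 0.043 for housekeeping genes. Housekeeping genes did not pass against CpG-matched genes (permutation adjusted p = 0.11), with the 5'-most TSS (0.69), within 2.5 kb (0.48) or without replicate 1 (0.094).

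Hox promoters carried narrow peaks, with a median of 872 covered bases (665 and 698 in replicates 1 and 2, n = 20 marked genes) and at most 1227 at Hoxa1, followed by Hoxa7 (1163) and Hoxd1 (1135). Vascular and meningeal genes had a median of 1612.5 bases (n = 14), with Foxc1, a meningeal regulator, at 4181, Pdgfrb, a pericyte receptor gene, at 2682 and Kcnj8, a potassium channel gene, at 2442. Choroid plexus and ependyma genes had a median of 1526 bases (n = 9), led by the ciliary gene Cfap126 (3313), the cilia regulator Foxj1 (2418) and the homeobox gene Otx2 (2315). Medians were 1405.5 for muscle (n = 8), 1344 for erythroid (n = 5), 1061 for germline (n = 3) and 451 for olfactory receptor genes (n = 3). These 7 lists were narrower than random lists by the same permutation test, with adjusted p of 6.3e-05 for Hox, 0.01 for vascular, 0.024 for choroid plexus, 0.011 for muscle, 0.038 for erythroid, 0.038 for germline and 0.0018 for olfactory receptor genes. Against CpG-matched genes, Hox (5.4e-04), germline (0.0085) and olfactory receptor genes (0.02) passed the permutation test, while vascular (adjusted p = 0.34), choroid plexus (0.16), muscle (0.26) and erythroid genes (0.34) did not. Over all genes in place of marked genes, vascular, choroid plexus, muscle, erythroid and germline genes did not pass. Oligodendrocyte genes did not pass the test (median 2801, n = 11, permutation adjusted p = 0.52), although Olig2, a lineage regulator, had 8142 covered bases, the growth factor receptor gene Pdgfra 5068 and Nkx2-2 3916. Regulators of midbrain, hindbrain and spinal cord had a median of 2012 (n = 17, permutation adjusted p = 0.16), with Egr2, a hindbrain segment gene, at 4251, Gata3 at 3988 and Gata2 at 3629. These regulators were called narrower in each replicate's own list, with the 5'-most TSS and within 2.5 kb, but in no other setting. Microglia (1421, n = 3), liver (1284, n = 3) and intestine and pancreas genes (2791, n = 3) were not called either (permutation adjusted p = 0.11, 0.075 and 0.71).

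**Figure D2:**
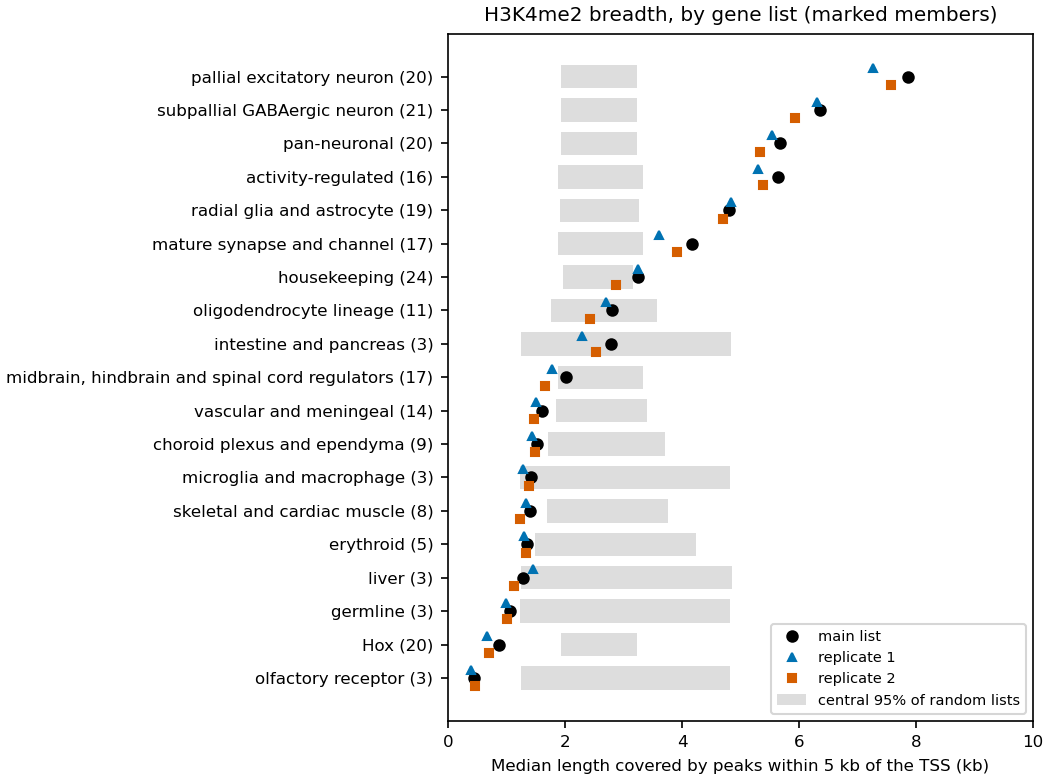
Median length covered by H3K4me2 peaks within 5 kb of the TSS (x axis, kb) for marked genes of 19 lists (y axis, number of marked genes in brackets); black points are the main list, blue triangles replicate 1, orange squares replicate 2, and grey bars hold the central 95% of random lists. The pallial median was 7864 bases and the Hox median 872.

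Pallial and subpallial genes were over-represented in the broadest domains of the mark. Peaks joined over gaps of up to 1 kb gave 29684 domains, of which the broadest 1% (297 domains of at least 7473 bases) held the promoters of 300 genes. In the main list the widest spanned 35950 bases at Meis2, a homeobox gene of striatal and other neurons, and the next 35452 bases at Dlx5 and Dlx6, homeobox genes of GABAergic neurons. After it came a domain of 34001 bases at Mir9-2. All 3 loci of miR-9, a microRNA of neural progenitors and neurons, were among the 15 widest, with 24994 bases at Mir9-1 and 23660 at Mir9-3. Between and below them came Pou3f3 (33129 bases), the cortical projection neuron regulator Satb2 (31905), the telencephalic regulator Foxg1 (30524), the progenitor factor gene Sox2 (29243), Nfib (28325), Bcl11a (28316) and the nuclear receptor genes Nr2f2 (26433) and Nr2f1 (24702). Further down were Dlx1 and Dlx2 (24054), Tcf4 (23866), Pou3f2 (22356), Lhx2 (21839), the corticospinal neuron regulator Bcl11b (21484), Mn1 (21476), Celf2 (20949), the noncoding gene Lncppara (19482), Nfia and its neighbour E130114P18Rik (19117), Nfix (18717) and Zeb2 (18625). Each of these 24 domains was also among the 100 broadest in each replicate, but widths and ranks moved. Foxg1 had 30655 bases in replicate 1 and 14430 in replicate 2, Bcl11b 38182 and 21991, Tcf4 12465 and 19941, Celf2 22160 and 12010 and Nr2f2 18577 and 28846. The widest domain was that of Bcl11b in replicate 1 and that of Dlx5 and Dlx6 (35412 bases) in replicate 2, where Meis2 had 35800 and 31635.

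Pallial genes were found in these domains in 14 of 20 cases (70.0%, exact 95% interval 45.7 to 88.1) against 2.0% of other marked genes, namely Bcl11b, Emx1, Emx2, Fezf2, Lhx2, Mef2c, Neurod2, Neurod6, Pou3f2, Pou3f3, Satb2, Slc17a6, Sox5 and Tbr1. Subpallial genes followed with 11 of 21 (52.4%, 29.8 to 74.3), namely Arx, Dlx1, Dlx2, Dlx5, Dlx6, Gad1, Gad2, Lhx6, Six3, Slc32a1 and Sp9. Radial glia genes had 6 of 19 (31.6%, 12.6 to 56.6), namely Hes1, Nfia, Nfib, Pax6, Sox2 and Sox9, and pan-neuronal genes 3 of 20 (15.0%), Celf4, Elavl4 and Tubb3. Counts in replicates 1 and 2 were 13 and 15, 11 and 10, 5 and 6, and 3 and 3. Fisher's exact test, two-sided, adjusted over 19 lists, gave log2 odds ratios of 6.80 (adjusted p = 1.1e-18), 5.76 (adjusted p = 6.2e-13), 4.55 (adjusted p = 9.7e-06) and 3.27 (adjusted p = 0.036). The pan-neuronal count did not pass for peaks with a -log10 q of at least 5 (10%, exact test adjusted p = 0.17) or with gaps of up to 3 kb (5%, 1). Gria2 and Grin2b of the synapse list (2 of 17, adjusted p = 0.15), Homer1 and Nr4a3 of the activity list (2 of 16, adjusted p = 0.15), Olig2 (1 of 11, adjusted p = 0.55) and Ywhaz (1 of 24, adjusted p = 0.93) were the other members in such domains, in numbers that did not pass the exact test. The synapse list did pass in the pooled list, in each replicate's own list (3 members in each) and with gaps of 0 or up to 3 kb. The activity list passed with these gaps and in the broadest 5%. Neither list passed in the remaining settings. None of the marked genes of the other 11 lists was in them, among them 20 Hox genes and 17 regulators of midbrain, hindbrain and spinal cord.

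**Figure D3:**
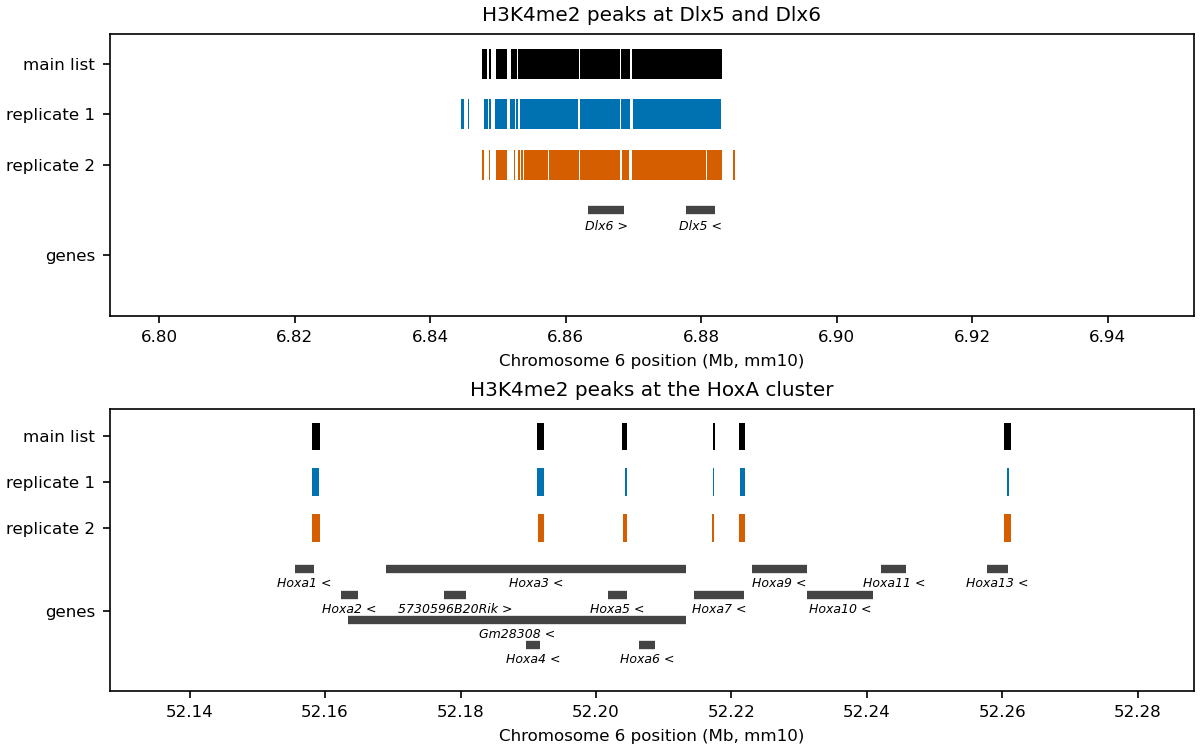
H3K4me2 peaks of the main list (black), replicate 1 (blue) and replicate 2 (orange) in 160 kb windows of chromosome 6 (x axis, position in Mb) at Dlx5 and Dlx6 (top) and the HoxA cluster (bottom); grey bars are genes, with arrowheads giving the strand. Peaks of the main list covered 33527 bases in the upper window and 5383 in the lower.

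Distal peaks, more than 2.5 kb from any annotated TSS, were more frequent around pallial, subpallial, radial glia and activity-regulated genes than around genes matched on territory length. The random lists were drawn from all protein-coding genes, marked or not. No setting restricted them to marked genes or matched them on CpG ratio. An excess common to marked or CpG-rich genes is therefore not separated here. Tcf4, a basic helix-loop-helix gene of neurons, had the most assigned peaks of any protein-coding gene in the main list, 26 (38 and 35 in replicates 1 and 2). It was followed by Gse1 (25; 26 and 40, more than Tcf4 in replicate 2), the forkhead gene Foxp1 (22), E130114P18Rik beside Nfia (20), Nfib (19), the teneurin gene Tenm3 (19), the lymphoid and neural factor gene Bach2 (17), and Adgrl2, Mef2c and Nfix (16 each). These counts are not scaled by territory, which was 539 kb for Tcf4, 705 kb for Foxp1 and 77.3 kb for Nfix. Pallial genes had a mean of 5.40 distal peaks (6.75 and 8.40 in replicates 1 and 2) against 0.95 in random lists matched on the length of a gene's territory, a ratio of 5.68. Subpallial genes had 4.00 against 0.857 (ratio 4.67) and radial glia genes 3.4 against 0.95 (3.58). Activity-regulated genes had 2.06 against 0.563 (3.67), regulators of midbrain, hindbrain and spinal cord 2.42 against 0.895 (2.71), oligodendrocyte genes 1.44 against 0.556 (2.60) and pan-neuronal genes 2.75 against 1.15 (2.39). Olfactory receptor genes had fewer than matched genes (0.0192 against 0.170). The two-sided permutation test, adjusted over 19 lists, gave 0.0019 for pallial and subpallial genes, both from the smallest p that 10000 lists can give, 0.0025 for radial glia, 0.0076 for activity-regulated, 0.017 for midbrain and hindbrain, 0.023 for pan-neuronal, 0.041 for oligodendrocyte and 0.0076 for olfactory receptor genes. The oligodendrocyte excess was lost in 6 of 8 other settings, that of midbrain and hindbrain regulators in 3, and the pan-neuronal one beyond 5 kb from a TSS (permutation adjusted p = 0.064) and with assignment within 50 kb (0.088).

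No difference in distal peaks passed the threshold for the other 11 lists. Means were 0.833 for synapse genes against 0.778 in matched lists (permutation adjusted p = 0.99), 1.15 for vascular against 0.850 (0.71), 1.07 for choroid plexus against 0.714 (0.71), 0.857 for intestine and pancreas against 0.571 (0.71) and 0.625 for housekeeping genes against 0.25 (0.2). They were 0.444 for microglia against 0.333 (permutation adjusted p = 0.91), 0.350 for liver against 0.350 (1), 0.286 for erythroid against 0.214 (0.995), 0.182 for muscle against 0.273 (0.71), 0.150 for germline against 0.400 (0.31) and 0.0769 for Hox genes against 0.103 (0.89). In all, 14317 of the peaks on chromosomes (39.2%) were distal, and 11450 were assigned to the nearest protein-coding TSS within 100 kb, at 5661 genes. Nearest-gene assignment does not show which gene a distal element controls.

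**Figure D4:**
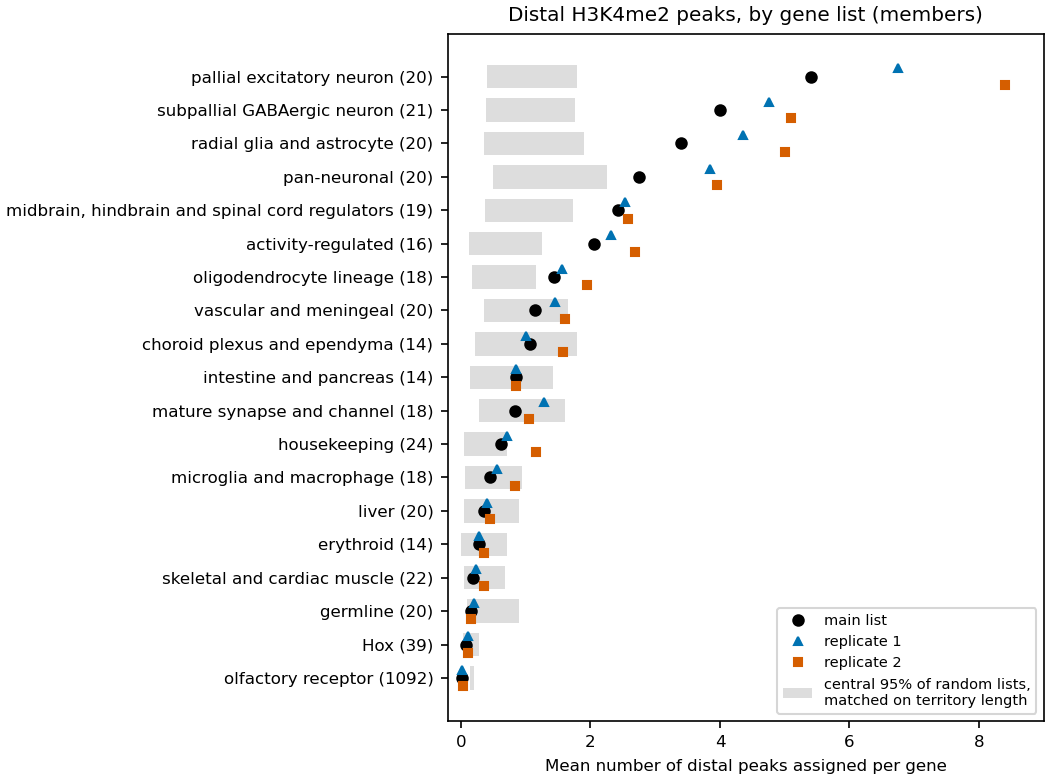
Mean number of distal H3K4me2 peaks assigned per gene (x axis) for 19 lists (y axis, number of genes in brackets); black points are the main list, blue triangles replicate 1, orange squares replicate 2, and grey bars hold the central 95% of random lists matched on territory length. The pallial mean was 5.40 and the liver mean 0.350.

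Around the summits of distal peaks, the E-box CAGCTG, a site of basic helix-loop-helix factors, occurred in 15.7% of 200-base windows and in 9.07% of windows 3 kb away from the summits. The Rfx site, bound by regulators of ciliary and neuronal genes, occurred in 2.28% (1.44% nearby) and the Sox site ACAAAG in 17.8% (16.5% nearby, and 14.9% for its reversed sequence). These 3 of 11 motifs were higher than nearby by Fisher's exact test, two-sided, adjusted over 11 motifs, with ratios of 1.74 (adjusted p = 9.6e-65), 1.59 (adjusted p = 4.6e-07) and 1.08 (adjusted p = 0.0096). The reversed sequences of CAGCTG and of the Rfx, nuclear factor I and CTCF sites hold a CpG, which is scarce in the genome, so the excess over the reverse says nothing for them and is left out. Against the reversed sequence, the exact test called the E-box CAGATG (16.4% against 4.19%, adjusted p = 4.2e-269), the homeodomain site TAATTA (5.87% against 4.49%, adjusted p = 3.7e-07) and the Mef2 site (0.496% against 0.265%, adjusted p = 0.0027) higher. Their shares nearby were 15.6% (exact test adjusted p = 0.088), 5.89% (adjusted p = 0.96) and 0.349% (adjusted p = 0.11). The AP-1 site was more frequent than its reverse (4.75% against 3.83%, exact test adjusted p = 2.4e-04) but less frequent than nearby (5.87%, ratio 0.809, adjusted p = 6.9e-05). Likewise the Gata site exceeded its reverse (8.38% against 7.26%, exact test adjusted p = 7.3e-04) and fell short of nearby windows (11.4%, ratio 0.738, adjusted p = 2.9e-16). Matches to the nuclear factor I, CTCF and Hnf4 sites were few (6, 1 and 26 windows of 14317), and none passed the test against nearby windows (exact adjusted p = 0.17, 0.45 and 0.56). Nearby windows were not matched on base composition, and a short sequence match does not show that a factor is bound.

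The strongest peak of the main list, with a fold of 73.8 (58.6 and 63.7 in replicates 1 and 2), covered the promoter of Egr1, an early response gene, at 34858983 to 34863747 on chromosome 18. The next, of fold 71.4, lay on chromosome 5 at 52112153 to 52116866, 446 bases from the noncoding gene Gm43177 and away from any protein-coding promoter. Promoters of Adgrg6, an adhesion receptor gene (fold 67.2), Emilin2, a matrix gene (fold 66.8), and E2f8, a cell cycle repressor gene (fold 65.5), held the other 3 of the 5 highest. All 5 had folds of at least 50.5 in both replicates.

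Promoters held 53.1% of the peaks of the main list (19372 peaks), against 9.88% after random placement, a ratio of 5.38. Intergenic sequence held 19.7% (48.4% at random), introns 21.9% (33.2%) and exons 5.31% (8.50%). The 2 replicates had 48.7 and 46.9% of peaks at promoters, 26.0 and 27.4% in introns, 19.9 and 20.1% in intergenic sequence and 5.38 and 5.67% in exons. The main list covered 50.01 Mb, or 1.89% of the known bases of the chromosomes, in 36483 peaks on chromosomes of median width 959 bases.

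The X chromosome carried 6.30 peaks per Mb, against 14.8 on the autosomes, a ratio of 0.426 (0.415 and 0.388 in replicates 1 and 2). Of its protein-coding promoters 51.6% were marked, against 68.1% on the autosomes. The Y chromosome carried 9 peaks, with 2.19% of its promoters marked. Chromosome 11 had the highest density (21.9 peaks per Mb) of the autosomes and chromosome 14 the lowest (11.1). The labels describe pools of animals of both sexes, and no test between sexes was possible.

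The 2 replicates shared most peaks. Of the peaks of replicate 1 on chromosomes, 82.2% (34788 of 42299) overlapped a peak of replicate 2, and 80.4% of those of replicate 2 (37971 of 47242) overlapped one of replicate 1, against 4.06 and 3.39% after random placement. The Jaccard index of covered bases was 0.776 (0.00995 at random). Fold enrichment of 34788 overlapping pairs correlated at 0.912 (Pearson, log2 scale) and 0.897 (Spearman), and the log2 ratio between replicates had an SD of 0.52. Sharing rose with enrichment, from 43.0 and 42.7% in the lowest of 5 classes of peaks by fold to 100% in the highest class of each replicate. Peaks found in one replicate only had a median fold of 3.5 and 3.42 and a median width of 261 and 214 bases, beside 12.3 and 10.4 and 973 and 803 bases for shared peaks.

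**Figure D5:**
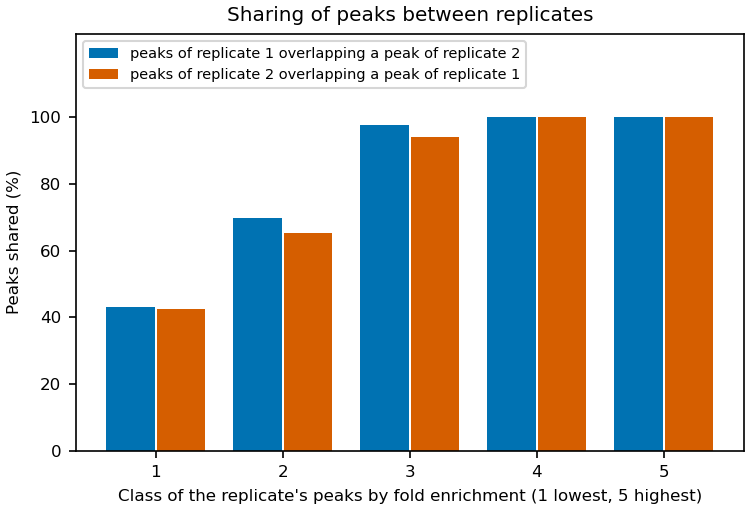
Share of peaks of one replicate that overlap a peak of the other (y axis, percent) by class of fold enrichment within the replicate (x axis, 5 classes, 1 lowest to 5 highest); blue bars are replicate 1 and orange bars replicate 2. Sharing rose from 43.0 and 42.7% to 100%.

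At the level of genes, 98.7% of protein-coding promoters had the same call in both replicates. There were 14534 marked in both, 102 in replicate 1 only and 187 in replicate 2 only. The excess in replicate 2 had a log2 ratio of 0.87 (exact McNemar test, two-sided, p = 6.5e-07). It was not found with lists of equal length (131 in replicate 1 only and 142 in replicate 2 only, exact McNemar p = 0.55). With a -log10 q of at least 5 the numbers were 100 and 95 (exact McNemar p = 0.77). Depth is not known from peak lists, and the list of replicate 2 held 47258 peaks against 42315 in replicate 1.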

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

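In this part the McNemar test on lists of equal length (a planned setting, put to this use once its result had been seen), the domain test with 1 member per 100 kb, the comparison of pallial and subpallial breadth with CpG-matched genes and its comparison with midbrain, hindbrain and spinal cord regulators were tests chosen after the results were seen. The other tests were written down before their results were seen. The design has 1 group, so no biological difference between samples was tested for any pattern.

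Signal outside the sequence and peaks used for the comparisons was found in 2 places. Unplaced contigs held 13 peaks of the main list, on 6 contigs, with a median fold of 8.10 and a highest of 13.4, and 4 of them lay on a contig assigned to the X chromosome. They were picked out because no comparison used contigs. The pooled list held 11151 peaks outside the main list, picked out because the main comparisons did not use them. Those on chromosomes (11148) had a median fold of 2.91 and a median width of 225 bases, 14.5% lay at promoters and 51.3% in introns, and 659 had a -log10 q of at least 5. They marked 160 protein-coding genes that the main list left unmarked, among them 5 list members: S100b, Lum, Pax7, Hoxb5 and Hoxc10. Only 146 of them overlapped peaks of both replicates, while 3705 overlapped replicate 1 alone, 3990 replicate 2 alone and 3310 neither.

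More promoters were marked in replicate 2 alone (187) than in replicate 1 alone (102). With the same number of peaks kept from each list the numbers were 142 and 131 (exact McNemar p = 0.55), so a longer list of weak peaks in replicate 2 is a candidate explanation. Promoters strongly marked in replicate 2 only are not the main source: 16.0% of the 187 (30 promoters, exact 95% interval 11.1 to 22.1) had a -log10 q of at least 5, where over 50% had been asked for. A difference in depth between the libraries stays open, since peak lists do not give depth.

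Pallial and subpallial genes, 41 in all, lay in the broadest domains in 25 cases (61.0%). A high CpG ratio at the TSS did not account for their breadth within 5 kb, since the median of 7026 covered bases stood against 2467 in CpG-matched lists (central 95% 2097 to 2955, permutation p = 2e-05, the smallest possible). The domain count itself was not compared with CpG-matched genes. The length of CpG-rich sequence was not matched either, so its part in the domains is not decided here. Neighbouring members counted more than once did not account for the domain count: with 1 member per 100 kb, 23 of 39 genes (59.0%) lay in such domains (Fisher's exact p = 1.8e-29). Breadth shared by developmental regulators of any brain region was argued against by the median of 2012 for 17 midbrain, hindbrain and spinal cord regulators (permutation p = 1e-05, the smallest possible, for a difference of 5014). Activity of these genes in many forebrain cells may underlie the breadth, a hypothesis that stays open because expression was not measured here.

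The X chromosome had fewer peaks per Mb than the autosomes (ratio 0.426). Fewer promoters on the X cannot be the whole cause, since the ratio for distal peaks was lower still (0.268, with 0.255 and 0.225 in replicates 1 and 2), and neither can CpG-poor promoters, since 51.6% of X promoters were marked against 56.0% in CpG-matched autosomal lists (central 95% 54.0 to 57.9). Lower enrichment on the X was found, with a median fold at CpG-rich marked promoters 0.562 times the autosomal value (17.6 against 31.4, and 0.566 in each replicate), but whether the fold is relative to a control library, which would itself carry the X copy number, is not given in the sources used here, so this ratio alone does not speak for or against a cell's number of active X chromosomes. A candidate explanation that stays open is 1 active X per cell, and a test within the X, where copy number is shared, went with it: 5 genes known to escape inactivation (Ddx3x 30.7, Kdm5c 29.6, Kdm6a 23.0, Pbdc1 18.9 and Eif2s3x 18.4) had a median fold of 23.0 against 17.5 for 367 other CpG-rich X promoters (permutation p = 0.037). In replicate 2, Eif2s3x (12) and Pbdc1 (14.0) lay below the X median of 15.2, and the share of male and female cells was not used here.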

How the results depend on the processing

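In this part the setting of 1 member per 100 kb was chosen after the results were seen, the McNemar test on lists of equal length was planned but read as a test of list length only after its result was seen, and the cause of any change was not tested. Sharing of peaks (82.2 and 80.4% of replicates 1 and 2) became 79.2 and 76.9% when an overlap of 50% of the shorter peak was required, 90.0 and 92.1% for peaks with a -log10 q of at least 5, and 79.3 and 85.2% for lists of equal length. Location shares, in the order promoter, exon, intron and intergenic, were 44.1, 5.66, 28.8 and 21.5% in the pooled list and 58.2, 5.07, 18.0 and 18.7% with a -log10 q of at least 5. They were 60.8, 3.68, 17.3 and 18.3% with promoters of 2.5 kb and 58.0, 4.36, 25.2 and 12.4% by bases. Without replicate 1 or 2 they were 46.9 to 48.7, 5.38 to 5.67, 26.0 to 27.4 and 19.9 to 20.1%. With a CpG-matched background, 1 list in place of 7 was higher and 4 in place of 7 lower in promoter marking, and 3 in place of 7 lower in breadth (vascular, choroid plexus, muscle and erythroid genes no longer passed). In promoter marking, a list whose matched lists were at 100% could not be called higher. Lists lower in breadth numbered 4 with the 5'-most TSS and 2 over all genes, and 2 lists in place of 1 were lower in distal peaks without territory matching. The log2 excess of promoters in replicate 2 fell to 0.12 with lists of equal length (exact p = 0.55) and turned to -0.074 with a -log10 q of at least 5 (exact p = 0.77). The X ratio was 0.446 with a -log10 q of at least 5. Against windows 3 kb from the summit, 3 motifs in place of 8 were higher and 2 in place of 0 lower: the direction turned for TAATTA (5.87% against 5.89%), AP-1 (4.75% against 5.87%) and Gata (8.38% against 11.4%). The 8 include CAGCTG and Rfx, whose reversed sequences hold a CpG and are a poor control. CTCF sites, equal in the main list to their reverse, exceeded it without replicate 2 (0.0622%, with 0.0452% without replicate 1, which did not pass) and in whole peaks (0.629%). Their reverse holds a CpG and is a poor control, so these changes say nothing about CTCF sites.

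Over the 4 families of gene list tests, 576 of 641 single calls stayed on their side of the threshold, 43 no longer passed and 22 newly passed. Of the calls that passed in the main or the other setting, 0 reversed. Some that passed in neither turned in direction, as for midbrain and hindbrain regulators with a CpG-matched background (89.5% against 100%, main 89.5% against 66.8%) and oligodendrocyte breadth within 2.5 kb (2011 against 2345, main 2801 against 2482) and over all genes (1244.5 against 1835.5). Of the 150 that left out a replicate, 139 stayed, 4 no longer passed and 7 newly passed. Without replicate 1, the narrow breadth of erythroid genes (1335 bases, permutation adjusted p = 0.061), the breadth of housekeeping genes (2872, 0.094) and the distal excess of midbrain and hindbrain regulators (2.58, 0.08) no longer passed. Newly passing there were the narrow breadth of midbrain and hindbrain regulators (1651, permutation adjusted p = 0.03) and liver genes (310.0, 0.0032) and the distal excess of housekeeping genes (1.17, 0.045). Without replicate 2, the oligodendrocyte distal excess was lost (1.56, permutation adjusted p = 0.078), while the breadth of midbrain and hindbrain regulators (1786, 0.038) and fewer marked Hox promoters (48.7%, exact test adjusted p = 0.034) newly passed. Synapse genes in the broadest domains passed without either replicate (17.6%, exact test adjusted p = 0.031 and 0.026). With 1 member per 100 kb, no call changed in promoter marking, breadth or broadest domains, and the oligodendrocyte list no longer passed in distal peaks. Only 4 Hox genes were kept there, 1 per cluster, and all were marked, a direction opposite to that of the 39 genes but passing in neither case. They were the members at the lowest position of each cluster, and 4 genes are too few for an excess to pass, so this turn carries no weight. The oligodendrocyte distal excess was lost in 6 of 8 settings, the midbrain and hindbrain excess in 3, and the pan-neuronal excess in 2. Activity-regulated genes passed in the broadest 5% of domains (62.5%, exact test adjusted p = 2.6e-06) and with gaps of 0 or up to 3 kb (25% and 31.2%, adjusted p = 0.0022 and 1.4e-04). Of 66 motif calls 55 stayed, 3 no longer passed, 3 newly passed and 5 reversed. These calls include the 4 motifs whose reversed sequence holds a CpG and is a poor control. The correlations of fold between replicates (0.912 Pearson, 0.897 Spearman) became 0.923 and 0.911 with an overlap of 50% of the shorter peak, and 0.913 and 0.902 with -log10 p in place of fold. Peak lists carry no depth, so the effect of unequal depth on list length was not separated from a difference between samples.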

Other observations

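The 7 lists in this part were added after the design was fixed and before the result of any list was computed. Their breadth was not compared with CpG-matched genes, so a narrow or wide median here is not separated from CpG content. The marked members named are those with the most covered bases. All unmarked imprinted genes are named, and some of the 10 unmarked eye and retina genes, which were picked by no stated rule. The comparison of pallial and subpallial genes with diencephalon regulators was a test chosen after the results were seen.

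Regulators of the diencephalon, the part of the forebrain that forms thalamus and hypothalamus, were marked at all 16 promoters (100%, log2 odds ratio 4.04, adjusted p = 0.0033, Fisher's exact test, two-sided, over 7 lists). Their breadth did not pass the test, with a median of 2075.5 bases (random lists 2482, permutation adjusted p = 0.21), and Lef1, a Wnt effector gene, had the most (6770), followed by Lhx9 (6555), Tcf7l2 (5383) and Irx5 (4635). None of the 16 lay in the broadest domains, against 25 of 41 pallial and subpallial genes (Fisher's exact p = 1.2e-05). Their mean of 1.88 distal peaks stood against 1.00 in matched lists (permutation adjusted p = 0.24). Imprinted genes, expressed from 1 parental allele, were marked at 18 of 20 promoters (90.0%, log2 odds ratio 1.88, exact test adjusted p = 0.031), with Ndn and Slc22a18 unmarked, and the widest were Peg3 (6870 bases), Gnas (6475), Nnat (6288) and Mest (6115). Their median of 3227 bases did not pass the permutation test (adjusted p = 0.075). Eye and retina genes were marked at 5 of 15 promoters (33.3%, log2 odds ratio -1.94, adjusted p = 0.012), among them Rlbp1 (2165 bases), Gnat1 (1495), Nrl (1257) and Vsx1 (1113), but not Rho, Crx or Vsx2. Their median breadth of 1257 bases (n = 5 marked genes) was below that of random lists (permutation adjusted p = 0.025). None of these 3 lists passed against CpG-matched genes in promoter marking (100, 90.0 and 40% marked in matched lists, permutation adjusted p = 1 for each), and Gnas and Nnat were the 2 imprinted genes in the broadest domains (exact test adjusted p = 0.18). For the diencephalon list, matched lists at 100% left no room for an excess.

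The p-values in this paragraph count neighbouring genes as separate, since keeping 1 member per 100 kb was not run for the added lists. Clustered protocadherins, cell-surface genes of which a neuron uses a few, were marked at 13 of 56 promoters (23.2%, log2 odds ratio -2.71, adjusted p = 6.4e-11), against 69.6% of CpG-matched genes (permutation adjusted p = 7e-04). The widest marked promoters were those of Pcdhgc5 (7379 bases), Pcdhgc4 (7107), Pcdhgc3 (6213) and Pcdhac2 (5208), while the median of the 13 was 887 (permutation adjusted p = 6e-05, narrower than random lists). Pcdhgc5 and Pcdhgc4 lie next to each other and share a domain of 6907 bases. Clustered histone genes were marked at 59 of 67 promoters (88.1%, log2 odds ratio 1.80, adjusted p = 2.1e-04), fewer than the 97.0% of CpG-matched genes (permutation adjusted p = 0.0019). Their median breadth was 4046 bases (permutation adjusted p = 6e-05, from the smallest possible p), with Hist3h2a (8423), Hist1h4h (7498), Hist1h2af (6950) and Hist1h2ad (6822) first, and neighbouring histone genes shared peaks. In the broadest domains lay 5 histone genes (exact test adjusted p = 0.0496, close to the threshold). Hist1h4h and Hist1h2af, counted separately there, share a domain of 7604 bases. The mean of 0.194 distal peaks for histone genes exceeded the 0.0448 of matched lists (permutation adjusted p = 0.0077). Keratin genes were marked at 8 of 53 promoters (15.1%, log2 odds ratio -3.44, adjusted p = 3.4e-14), led by Krt10 (1876 bases), Krt1 (1511), Krt222 (883) and Krt18 (809), against 39.6% of CpG-matched genes (permutation adjusted p = 7e-04), with a median breadth of 806.5 bases (permutation adjusted p = 8e-05). Vomeronasal receptor genes were marked at 1 of 326 promoters, that of Vmn1r4 (0.307%, log2 odds ratio -8.84, exact test adjusted p = 1.9e-155), against 4.60% of CpG-matched genes (permutation adjusted p = 0.0035), and had fewer distal peaks than matched genes (0.0245 against 0.433, permutation adjusted p = 0.0077). The counts in replicates 1 and 2 were 16 and 16 for diencephalon, 18 and 18 for imprinted, 5 and 7 for eye, 15 and 16 for protocadherin, 59 and 60 for histone, 6 and 8 for keratin and 1 and 2 for vomeronasal receptor genes.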
